A study of Mus musculus with 28 samples.

How the data were processed

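RNA-seq was made from macrophages sorted from the pancreas of wild-type C57BL/6J mice in a pancreatitis model and its recovery, with lactate or PBS at days 1 and 3. Per the labels' protocols, libraries were built from 10 ng of total RNA. Each library was put into its group from its title, which also gives the replicate number: NC (3 libraries), D0 (5), D1 AP+PBS (6), D1 AP+Lac (6), D3 AP+PBS (4) and D3 AP+Lac (4). What the abbreviation NC stands for is not given, and it is used as a name.

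The authors deposited 1 table of FPKM values per gene and library, the unit being named in the file header. It lists 25301 genes by symbol and NCBI Gene ID, 18017 of them protein-coding, and no gene whose symbol begins with mt-. The submitters' processing notes name fastp and R 3.2.0. The aligner, the counting program and the genome build are not given in the sources used here, and no coordinates are reported. Without a stated counting rule, fragments of near-identical gene copies and of overlapping or antisense genes cannot be assigned with certainty. FPKM are relative to the mapped fragments of a library, so RNA of one cell type that takes a larger share of them lowers the values of other genes. The summed FPKM ran from 374871 to 460792.

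Depth was recovered from the values. Within a gene, FPKM values are whole multiples of what 1 fragment is worth, and 100% of the values came out whole (tolerance 0.0001). The totals ran from 33273303 to 41060490 fragments and lay very close to the denominators that the FPKM imply. Libraries of one group were compared pair by pair for a library deposited more than once: over 55 pairs the lowest chi-square per degree of freedom was 26.4, so no pair was close to sampling noise. Each library was entered as 1 replicate, although this check cannot show that the libraries came from separate animals.

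The tests were run on log2(FPKM + 1), since FPKM are not counts. This scale understates the change of genes with low values. Genes with FPKM of at least 1 in at least 3 libraries were kept (11960), with 1 entry per symbol. One limma 3.58.1 model (R 4.3.3) gave each of the 6 groups a mean, all 28 libraries shared the estimate of the spread, and variances were moderated with a trend and robustly. P-values are two-sided and were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Group values are mean FPKM ± SD. The 7 comparisons were day 0 against NC, day 1 PBS against day 0, day 3 PBS against day 1 PBS, day 3 PBS against NC, lactate against PBS at each day, and the difference between the 2 lactate effects.

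The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. There were 34 lists, 22 of macrophage states and pathways and 12 of cell type markers, and the lists share some genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The preset called 104 of 238 list tests. With an estimated correlation 0 of them were called, while 25 of 238 passed an unadjusted 0.05, so no list call in any comparison holds under that setting. Counts of members that rose or fell are given over all genes tested and adjusted over the list alone. Cell type content is the mean log2(FPKM + 1) of a marker list in a library, compared by a two-sided exact permutation test and adjusted over 72 tests (12 lists in 6 comparisons). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these.

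The genes named in each lactate comparison are the 10 highest and 10 lowest log2 fold changes among called genes with a mean FPKM of at least 5 in one of the 2 groups and a symbol that is not a gene model. All that met the rule are named where fewer did. Elsewhere the 5 highest and 5 lowest are named. From each list described, up to 4 members with the smallest p are named, and a set of macrophage, lactate and acinar genes fixed in advance is named whatever its result. Results of some list members that meet the rule are not reported here, none of them among the highest or lowest genes. The near-identical copies and plasma cell genes mentioned beside a result were singled out after the values were seen.

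The fit was tested on simulated data with known changes, using the real means and spread of the 11960 genes. For day 1 lactate against PBS it recovered 54.5%, 89.6% and 98.5% of genes with changes of 0.5, 1 and 2 on the log2 scale, and for day 3 48.5%, 92.5% and 98.5%. Of the genes called in the simulated data, 4.1% at day 1 and 6.4% at day 3 were false. The noise was drawn independently with 1 spread per gene for all groups. Divisions among the libraries of a group and single libraries far from the others were not simulated. In the real data recovery may therefore be lower and the share of false calls higher. The alternatives were another pseudocount, no filter or a stricter one, quantile and median-ratio scaling, removal of acinar genes, an acinar covariate, library quality weights, no variance trend, a fit of the compared groups alone, the replicate number as a block, and each library left out in turn. Alternatives added after the data were seen were voom on the recovered fragments, a lymphocyte covariate and the treatment of the day 1 libraries numbered 5 and 6.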

Results

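The deposited table held FPKM values (fragments per kilobase of transcript scaled to the mapped fragments of the library) for 25301 genes in 28 RNA-seq libraries of macrophages sorted from the pancreas of wild-type C57BL/6J mice in a model of acute pancreatitis. The libraries fell into 6 groups. The group labelled NC had 3 libraries and the day 0 group of the pancreatitis model had 5. At day 1 of recovery there were 6 libraries with PBS and 6 with lactate, and at day 3 there were 4 of each. The FPKM steps corresponded to 33273303 to 41060490 whole fragments per library. The labels do not say that the libraries of a group came from separate animals, so the p-values below measure only the spread between these libraries. For limma that spread was pooled over all 28 libraries and not taken from the compared groups alone. The gene holding the largest share of the summed FPKM took 1.23% to 3.23% of it. Adgre1, which encodes the macrophage surface marker F4/80, had a mean of 326 ± 67.2 (SD, n = 3) FPKM in NC, 313 ± 41.4 at day 0 (n = 5), 364 ± 67.9 and 231 ± 79.1 at day 1 with PBS and lactate (n = 6 each), and 142 ± 28.8 and 212 ± 70.6 at day 3 (n = 4 each).

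The first comparison asked how macrophages at day 0 of pancreatitis differed from the group labelled NC. Arg1 (NCBI Gene ID 11846), which encodes arginase 1, rose from 6.31 ± 8.92 (SD, n = 3) FPKM to 690.4 ± 235 (SD, n = 5) (log2 fold change 7.24, SE 0.78, adjusted p = 2.6e-08). The NC mean of Arg1 was 1.16 without NC 2 (at 16.6). Spp1, which encodes osteopontin, rose by a log2 fold change of 7.32 and the neutrophil-associated Lcn2 by 5.06, and the other genes among the 5 highest were Slfn4 (5.85) and Thbs1 (4.93). In the other direction, Retnla, which encodes a secreted protein of alternatively activated macrophages, fell from 2623 ± 674 (SD, n = 3) to 12.98 ± 5.58 (SD, n = 5) FPKM (log2 fold change -7.63), and the lectin genes Mgl2 and Cd209f fell with values of -7.07 and -6.23. Hpgd, a prostaglandin-degrading enzyme, and Rnase1, a secreted ribonuclease of the pancreas, completed the 5 lowest (-6.04 and -5.94). The largest adjusted p among these 10 genes was 3.4e-06 by limma.

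Members of several fixed lists changed at day 0. Of 31 cell cycle genes, 0 rose and 30 fell (0 and 30 adjusted over the list alone), with -2.88 for Stmn1 and -2.75 for Top2a. For the cell cycle genes, camera gave adjusted p = 8.8e-06, and adjusted p = 0.55 with an estimated correlation. Among 24 genes of tissue-resident macrophages, 2 rose and 17 fell (2 and 18 adjusted over the list alone), led by -5.54 for Timd4, -5.66 for Fcna and -4.86 for Lyve1. For the resident macrophage genes, camera gave adjusted p = 0.0020, and adjusted p = 0.55 with an estimated correlation. Of 22 monocyte genes, 17 rose and 2 fell (17 and 2 adjusted over the list alone), with 4.63 for Chil3, 3.94 for Vcan and 3.42 for Hp. For the monocyte genes, camera gave adjusted p = 4.1e-06, and adjusted p = 0.55 with an estimated correlation. Endoplasmic reticulum stress genes also moved: of 22, 15 rose and 1 fell (15 and 1 adjusted over the list alone), with 1.99 for Hspa5 and 1.88 for Pdia6. For the endoplasmic reticulum stress genes, camera gave adjusted p = 1.1e-07, and adjusted p = 0.55 with an estimated correlation. Of 27 interferon-stimulated genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone), with 2.93 for Irf7 and 2.29 for Rtp4. For the interferon-stimulated genes, camera gave adjusted p = 4.1e-06, and adjusted p = 0.55 with an estimated correlation. Among 20 antigen presentation genes, 1 rose and 10 fell (1 and 10 adjusted over the list alone), and the class II genes Cd74 and H2-Aa had values of -3.77 and -4.01. For the antigen presentation genes, camera gave adjusted p = 0.0051, and adjusted p = 0.55 with an estimated correlation. Lysosome genes split, 12 rose and 4 fell (12 and 4 adjusted over the list alone), with the cathepsin genes Ctsl at 3.33 and Ctsd at 2.69. For the lysosome genes, camera gave adjusted p = 2.1e-04, and adjusted p = 0.55 with an estimated correlation. The 28 reparative macrophage genes held both Arg1 and Retnla, and 7 rose and 16 fell (7 and 16 adjusted over the list alone). For the reparative macrophage genes, camera gave adjusted p = 0.29, and adjusted p = 0.69 with an estimated correlation.

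Markers of other cells were compared in these libraries. The mean log2(FPKM + 1) of the acinar markers was 3.03 ± 0.27 against 6.18 ± 0.32 in NC (SD, n = 5 and 3, two-sided exact permutation p = 0.018, adjusted p = 0.054), and the B and plasma cell markers were at 2.05 ± 0.48 against 4.75 ± 0.13 (two-sided exact permutation p = 0.018, adjusted p = 0.054 by the same test). T and NK cell markers were at 1.80 ± 0.47 against 3.57 ± 0.30 with the same exact p, dendritic cell markers at 2.82 ± 0.14 against 4.34 ± 0.07 and neutrophil markers at 3.08 ± 0.32 against 1.70 ± 0.26. Macrophage markers (8.78 ± 0.05 against 8.23 ± 0.09), fibroblast and stellate cell markers (1.17 ± 0.20 against 2.16 ± 0.14), endothelial cell markers (0.68 ± 0.11 against 1.47 ± 0.22), mast cell, basophil and eosinophil markers (0.41 ± 0.07 against 0.69 ± 0.05) and islet markers (0.04 ± 0.03 against 0.17 ± 0.02) gave this p as well. The smallest p that 5 against 3 libraries can give is 0.018, and none of these differences passed after adjustment over 72 tests. After median-ratio scaling, a setting chosen after the data were seen, 11 of the 12 lists passed by the exact permutation test, 3 higher and 8 lower (smallest adjusted p = 0.049), the erythroid and platelet markers being the other list. By limma, 2361 of 11960 genes were higher and 4948 lower at day 0. With the acinar marker level as a covariate 3474 genes were called, and the split was 3558 higher and 2755 lower after quantile normalization and 4039 higher and 3530 lower after median-ratio scaling, which moved the median log2 fold change of all genes by 0.27 and 0.25. Each fold change above lies relative to a median of -0.22 over all genes.

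The step from day 0 to day 1 with PBS described the first part of recovery. Arg1 fell from its day 0 level to 23.4 ± 10.8 (SD, n = 6) FPKM (log2 fold change -4.84, SE 0.65, adjusted p = 8.3e-07), and Mmp8, Slfn4, Lcn2 and Vcan fell with log2 fold changes of -4.68, -4.28, -4.15 and -4.15. The 5 highest were Jchain and Mzb1, which plasma cells express, Pou2af1, a B cell transcriptional coactivator, Rnase1 and Stmn1, a regulator of microtubules in dividing cells, with 4.58, 4.11, 3.91, 4.14 and 3.65 (largest adjusted p among the 10 genes = 1.1e-04 by limma). Pou2af1 had a value of -0.06 with the lymphocyte marker level as a covariate, an alternative chosen after the data were seen. Retnla rose to 71.7 ± 19.7 (SD, n = 6) FPKM, a log2 fold change of 2.43, and Mrc1, the mannose receptor, rose by 1.06.

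Of the 31 cell cycle genes, 31 rose and 0 fell (31 and 0 adjusted over the list alone), with 3.44 for Ccnb2, 2.86 for Cenpa and 2.81 for Nusap1. For the cell cycle genes, camera gave adjusted p = 8.3e-10, and adjusted p = 0.65 with an estimated correlation. Of 22 monocyte genes, 3 rose and 17 fell (3 and 17 adjusted over the list alone), and Hp and Fn1 had values of -3.12 and -2.14. For the monocyte genes, camera gave adjusted p = 1.2e-06, and adjusted p = 0.48 with an estimated correlation. Endoplasmic reticulum stress genes went the other way: 1 rose and 15 fell (1 and 15 adjusted over the list alone), with -1.93 for Calr and -1.99 for Hspa5. For the endoplasmic reticulum stress genes, camera gave adjusted p = 8.3e-10, and adjusted p = 0.48 with an estimated correlation. Of 20 antigen presentation genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone), with 2.34 for Cd74 and 2.51 for H2-Aa. For the antigen presentation genes, camera gave adjusted p = 0.0032, and adjusted p = 0.48 with an estimated correlation. Among 24 resident macrophage genes, 15 rose and 3 fell (16 and 3 adjusted over the list alone), including 3.13 for Pltp, 3.05 for Fcna and 2.09 for Igf1. For the resident macrophage genes, camera gave adjusted p = 0.060, and adjusted p = 0.69 with an estimated correlation. Of the 27 interferon-stimulated genes, 1 rose and 14 fell (1 and 14 adjusted over the list alone). For the interferon-stimulated genes, camera gave adjusted p = 7.4e-05, and adjusted p = 0.69 with an estimated correlation.

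Over the same step the B and plasma cell markers stood at 4.98 ± 0.81 against 2.05 ± 0.48 at day 0 (mean log2(FPKM + 1), SD, n = 6 and 5, two-sided exact permutation p = 0.0022, adjusted p = 0.031). T and NK cell markers (3.94 ± 0.54 against 1.80 ± 0.47), dendritic cell markers (3.90 ± 0.23 against 2.82 ± 0.14) and, in the other direction, neutrophil markers (1.91 ± 0.33 against 3.08 ± 0.32) gave the same exact p and adjusted p. Acinar markers were at 4.90 ± 0.91 against 3.03 ± 0.27 and fibroblast and stellate cell markers at 2.86 ± 0.87 against 1.17 ± 0.20 (each two-sided exact permutation p = 0.0065, adjusted p = 0.043). Mast cell, basophil and eosinophil markers were at 0.97 ± 0.25 against 0.41 ± 0.07 (two-sided exact permutation p = 0.0043, adjusted p = 0.038) and macrophage markers at 8.51 ± 0.21 against 8.78 ± 0.05 (two-sided exact permutation p = 0.019, adjusted p = 0.056). After median-ratio scaling 9 lists passed against 7, the macrophage and the erythroid and platelet markers being added. limma called 5147 genes higher and 2374 lower at day 1. That count was 4992 with the acinar covariate and 4659 with the lymphocyte covariate, and the direction split was 2835 higher and 3666 lower after quantile normalization and 3625 higher and 4263 lower after median-ratio scaling (shifts of the median over all genes of -0.23 and -0.22).

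Between day 1 and day 3 with PBS, lysosome genes and macrophage markers were mostly lower and dendritic cell markers mostly higher. Stab1, which encodes the scavenger receptor stabilin 1, fell from 345 ± 156 (SD, n = 6) to 48.4 ± 9.77 (SD, n = 4) FPKM (log2 fold change -2.68, SE 0.30, adjusted p = 4.1e-06). The other genes among the 5 lowest were Nxpe5, Chil3, Spp1 and the lipid receptor gene Trem2, with log2 fold changes of -2.49, -2.42, -2.28 and -2.14. The 5 highest were Ly6i (2.99) and the exocrine pancreas genes Pdia2, Prss1, Prss3b and Cel (3.08, 3.00, 2.68 and 2.57), with a largest adjusted p among the 10 genes of 0.0064. Adgre1 and Csf1r, the receptor for the macrophage growth factor CSF1, fell with values of -1.35 and -1.07, while Retnla rose by 1.92.

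Of 29 lysosome genes, 0 rose and 22 fell (0 and 24 adjusted over the list alone), with -1.92 for Ctsd, -1.65 for Ctsb and -0.94 for Gusb. For the lysosome genes, camera gave adjusted p = 1.3e-15, and adjusted p = 0.25 with an estimated correlation. Among 12 macrophage markers, 1 rose and 9 fell (1 and 9 adjusted over the list alone), including -1.21 for Cd68 and -1.40 for Mertk. For the macrophage markers, camera gave adjusted p = 3.5e-06, and adjusted p = 0.25 with an estimated correlation. Of 24 resident macrophage genes, 1 rose and 12 fell (2 and 12 adjusted over the list alone), with -1.81 for Cbr2 and -1.57 for Selenop. For the resident macrophage genes, camera gave adjusted p = 5.7e-06, and adjusted p = 0.41 with an estimated correlation. In the other direction, of 20 antigen presentation genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone), with 0.89 for Cd74 and 0.67 for Tap2. For the antigen presentation genes, camera gave adjusted p = 4.8e-04, and adjusted p = 0.25 with an estimated correlation. Of 27 interferon-stimulated genes, 14 rose and 0 fell (19 and 0 adjusted over the list alone), with 1.75 for Ifi205. For the interferon-stimulated genes, camera gave adjusted p = 7.0e-04, and adjusted p = 0.81 with an estimated correlation. Of 19 T and NK cell markers, 15 rose and 0 fell (18 and 0 adjusted over the list alone), with 2.47 for Gzma and 2.11 for Ncr1, and of 16 dendritic cell markers, 13 rose and 0 fell (14 and 0 adjusted over the list alone), with 1.70 for Clec9a and 1.59 for Xcr1. For the T and NK cell markers, camera gave adjusted p = 3.5e-06, and adjusted p = 0.45 with an estimated correlation. For the dendritic cell markers, camera gave adjusted p = 1.6e-06, and adjusted p = 0.15 with an estimated correlation.

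Per library, macrophage markers were at 7.71 ± 0.32 against 8.51 ± 0.21 at day 1 (SD, n = 4 and 6, two-sided exact permutation p = 0.0048, adjusted p = 0.038), and dendritic cell markers at 4.89 ± 0.15 against 3.90 ± 0.23 and endothelial cell markers at 1.60 ± 0.33 against 0.95 ± 0.12 gave the same exact p and adjusted p. Acinar markers, at 6.34 ± 1.03 against 4.90 ± 0.91, and T and NK cell markers, at 5.21 ± 0.22 against 3.94 ± 0.54, did not pass after adjustment (two-sided exact permutation p = 0.052, adjusted p = 0.10 and two-sided exact permutation p = 0.0095, adjusted p = 0.053). After median-ratio scaling the T and NK cell markers passed, as did the erythroid and platelet markers, at 0.73 ± 0.05 against 0.93 ± 0.08 before it. By limma 2569 genes were higher and 1534 lower at day 3, and 1689 were called with the lymphocyte covariate. The split was 1771 higher and 2185 lower after quantile normalization and 1662 higher and 2186 lower after median-ratio scaling, each of which moved the median of all genes by -0.11.

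At day 3 with PBS the macrophages still differed from the group labelled NC. Lyve1, a hyaluronan receptor of resident macrophages, was at 15.1 ± 5.30 (SD, n = 4) FPKM against 285 ± 81.7 (SD, n = 3) (log2 fold change -4.16, SE 0.41, adjusted p = 5.7e-08). Ccn1, Cd209g, Cd209f and Mmp9 were the other genes among the 5 lowest (-4.25, -3.66, -3.58 and -3.56), and Retnla had not returned to its NC level (log2 fold change -3.28, adjusted p = 2.5e-06). The 5 highest were the pancreatic injury-associated lectin genes Reg3b and Reg3a, the trypsinogen genes Prss1 and Prss3, and Gzma of cytotoxic lymphocytes, with 4.39, 3.97, 4.23, 3.35 and 3.76 (largest adjusted p among the 10 genes = 9.6e-04). Reads of Prss1 and Prss3, of Reg3a and Reg3b, and of the Cd209 genes can be shared between near-identical copies, so these values are uncertain for each copy.

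Of 24 resident macrophage genes, 1 rose and 18 fell (2 and 19 adjusted over the list alone), with -3.40 for Timd4, -2.37 for F13a1 and -2.34 for Gas6. For the resident macrophage genes, camera gave adjusted p = 1.9e-13, and adjusted p = 0.17 with an estimated correlation. Of 19 T and NK cell markers, 15 rose and 0 fell (16 and 0 adjusted over the list alone), with 3.17 for Gzmb and 2.29 for Ncr1. For the T and NK cell markers, camera gave adjusted p = 7.3e-09, and adjusted p = 0.39 with an estimated correlation. Of 27 interferon-stimulated genes, 17 rose and 0 fell (24 and 0 adjusted over the list alone), with 3.15 for Ifi44 and 2.69 for Irf7. For the interferon-stimulated genes, camera gave adjusted p = 4.9e-07, and adjusted p = 0.69 with an estimated correlation. Among 26 immediate-early and dissociation-stress genes, 2 rose and 12 fell (3 and 17 adjusted over the list alone), with -1.32 for Jun and -2.03 for Hspa1a. For the immediate-early and dissociation-stress genes, camera gave adjusted p = 6.2e-05, and adjusted p = 0.63 with an estimated correlation. Per library, T and NK cell markers were at 5.21 ± 0.22 against 3.57 ± 0.30 in NC (SD, n = 4 and 3, two-sided exact permutation p = 0.029, adjusted p = 0.066), where 0.029 is the smallest p that this design allows. Fibroblast and stellate cell markers (3.44 ± 0.37 against 2.16 ± 0.14), dendritic cell markers (4.89 ± 0.15 against 4.34 ± 0.07), mast cell, basophil and eosinophil markers (1.02 ± 0.13 against 0.69 ± 0.05) and, in the other direction, erythroid and platelet markers (0.73 ± 0.05 against 1.10 ± 0.09) gave the same exact p and adjusted p. Macrophage markers were at 7.71 ± 0.32 against 8.23 ± 0.09 and B and plasma cell markers at 5.56 ± 0.35 against 4.75 ± 0.13 (each two-sided exact permutation p = 0.057, adjusted p = 0.10). Although trypsinogen genes were among the 5 highest, the acinar markers as a list were at 6.34 ± 1.03 against 6.18 ± 0.32 (two-sided exact permutation p = 0.80, adjusted p = 0.88). limma called 1236 genes higher and 1299 lower. The call count fell to 1188 without the NC library 3 and 1628 without NC 1, was 4489 with library quality weights (2627 higher and 1862 lower), and split 760 higher and 1590 lower after median-ratio scaling.

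The main question of the study was what lactate did to these macrophages. At day 1, interferon-stimulated genes were higher with lactate than with PBS, and Cxcl1 and Cxcl2, which encode chemokines that attract neutrophils, were lower. Isg15 (NCBI Gene ID 100038882), a ubiquitin-like interferon-induced protein, was at 490.2 ± 322 (SD, n = 6) FPKM with lactate and 157 ± 250.1 (SD, n = 6) with PBS (log2 fold change 2.60, SE 0.62, adjusted p = 0.014). The chemokine gene Cxcl10 had the largest log2 fold change among the called genes that met the naming rule, with 379 ± 232 against 127 ± 212 FPKM (log2 fold change 2.79, SE 0.73, adjusted p = 0.019). The PBS means rested in part on 1 library, being 57.6 without D1 AP+PBS 5 (at 656) for Isg15 and 42.9 without D1 AP+PBS 5 (at 550.3) for Cxcl10. The log2 fold change of Isg15 was 2.27 (adjusted p = 0.058) without D1 AP+PBS 1 and 2.41 (adjusted p = 0.054) without D1 AP+PBS 4. That of Cxcl10 was 2.46 (adjusted p = 0.069) without D1 AP+PBS 1 and 2.58 (adjusted p = 0.064) without D1 AP+PBS 4. The other 8 of the 10 highest were Slfn4 (2.66), Cxcl9 (2.62), Ifit2 (2.62), Tgtp1 (2.59), Acod1 (2.49), Iigp1 (2.48), Ly6i (2.40) and Ifit3 (2.39), of which Acod1 makes the metabolite itaconate and Tgtp1 and Iigp1 are interferon-induced GTPases. Cxcl1 and Cxcl2 fell with log2 fold changes of -2.02 and -1.45, Cxcl2 being at 121 ± 43.9 against 359 ± 171 FPKM. The other 8 of the 10 lowest were Gdf15 (-1.61), Tnfsf9 (-1.29), Mt1 (-1.15), Stab1 (-1.13), Jdp2 (-1.12), Gdpd1 (-1.11), Tns1 (-1.10) and Klf9 (-1.09), and the largest adjusted p among the 20 genes was 0.037 by limma. Ifit3 has a near-identical copy, Ifit3b, and Ly6i lies in a multigene family, so both values are uncertain for the single gene.

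The 12 day 1 libraries did not form one set. In the libraries numbered 5 and 6 of both treatments the acinar markers were at 3.63 to 4.28 (mean log2(FPKM + 1)) against 4.31 to 5.61 in numbers 1 to 4, and the cell cycle genes at 3.16 to 3.67 against 3.94 to 5.11. The labels give no batch, and this division was noticed in the data. With numbers 1 to 4 alone the log2 fold changes of Isg15, Cxcl10, Cxcl1 and Stab1 were 3.36, 3.89, -2.53 and -1.75, and with numbers 5 and 6 alone they were 1.08, 0.59, -1.002 and 0.12. Cxcl9 and Ly6i, too, had values near or below 0 in numbers 5 and 6 (-0.0040 and -0.25), and the signs of Pdcd1lg2 and Pltp, described further on, also turned there (-0.023 and 0.041). Within numbers 1 to 4, 1959 higher and 1467 lower genes were called, and 1510 were called in all 12 libraries with the division as a batch term. With 2 libraries against 2, numbers 5 and 6 gave 0 genes by limma and 394 of 11960 at an unadjusted p under 0.05. That is a smaller share than the 0.05 expected with no effect, so the 394 are no sign of an effect there.

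Of 27 interferon-stimulated genes, 26 rose and 0 fell (27 and 0 adjusted over the list alone), with 2.07 for Zbp1 and 2.16 for Ifi205. For the interferon-stimulated genes, camera gave adjusted p = 2.6e-18, and adjusted p = 0.30 with an estimated correlation. The PBS library D1 AP+PBS 5 had a mean log2(FPKM + 1) of 7.32 over these genes, within the 5.91 to 7.92 of the 6 lactate libraries. D1 AP+PBS 6, at 5.88, lay just below that range, and D1 AP+PBS 1 to 4 were at 3.97 to 4.53. The median log2 fold change was 1.88, with 2.42 in numbers 1 to 4 and 0.91 in numbers 5 and 6. Of 22 monocyte genes, 4 rose and 1 fell (8 and 3 adjusted over the list alone), with 2.10 for Ly6c2 and 1.76 for Plac8, and the medians in the 2 sets were 0.83 and -0.09. For the monocyte genes, camera gave adjusted p = 0.0094, and adjusted p = 0.56 with an estimated correlation. Among 20 antigen presentation genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with the peptide transporter genes Tap1 at 0.91 and Tap2 at 0.72 (medians 0.42 and 0.07). For the antigen presentation genes, camera gave adjusted p = 7.0e-04, and adjusted p = 0.30 with an estimated correlation. Of 24 resident macrophage genes, 0 rose and 5 fell (0 and 12 adjusted over the list alone), with -1.06 for Gas6, -0.94 for F13a1 and -0.84 for Pltp (medians -0.92 and 0.0030). For the resident macrophage genes, camera gave adjusted p = 2.3e-08, and adjusted p = 0.30 with an estimated correlation. Of 29 lysosome genes, 0 rose and 2 fell (0 and 15 adjusted over the list alone), with -0.58 for Npc1 and -0.66 for Atp6v0d2 (medians -0.53 and 0.02). For the lysosome genes, camera gave adjusted p = 1.7e-07, and adjusted p = 0.43 with an estimated correlation. Immediate-early and dissociation-stress genes went both ways, as 3 rose and 8 fell (4 and 13 adjusted over the list alone), with -0.70 for Jun and -0.97 for Egr1 (medians -0.52 and -0.11). For the immediate-early and dissociation-stress genes, camera gave adjusted p = 0.0040, and adjusted p = 0.61 with an estimated correlation.

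Genes used to describe macrophage polarization did not move as one group. Of 28 reparative macrophage genes, 3 rose and 4 fell (4 and 10 adjusted over the list alone) (medians -0.83 and 0.10), with Pdcd1lg2 and Socs2 higher (0.88 and 0.81) and Mrc1 lower (-0.84, adjusted p = 0.039). For the reparative macrophage genes, camera gave adjusted p = 0.0077, and adjusted p = 0.41 with an estimated correlation. Arg1 was at 19.9 ± 9.45 FPKM with lactate (SD, n = 6) and did not pass the test (log2 fold change -0.27, adjusted p = 0.84), nor did Chil3 (0.25) or Retnla (-0.77). Of 27 proinflammatory genes, 5 rose and 3 fell (5 and 4 adjusted over the list alone) (medians 0.03 and -0.10), while the list mean was 0.16 and the list median -0.12. For the proinflammatory macrophage genes, camera gave adjusted p = 0.89, and adjusted p = 1 with an estimated correlation. Nos2, inducible nitric oxide synthase, rose by 1.67 (adjusted p = 0.047), whereas Il1b and Tnf had values of -0.12 and -0.64 that did not pass. Nos2 was low in FPKM and its means rested in part on single libraries. They were 4.22 with lactate (2.71 without D1 AP+Lac 3, at 11.8) and 0.457 with PBS (0.036 without D1 AP+PBS 5, at 2.56). Among 15 genes of lactate transport, sensing and conversion, 0 rose and 0 fell (0 and 0 adjusted over the list alone). For the lactate transport, sensing and conversion genes, camera gave adjusted p = 1, and adjusted p = 1 with an estimated correlation. The lactate transporter genes Slc16a1 and Slc16a3 had values of 0.36 and 0.38, and Ldha of 0.22. Of 17 histone acyltransferase and deacylase genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone), Sirt2 being the gene that fell (-0.32). For the histone acyltransferase and deacylase genes, camera gave adjusted p = 0.44, and adjusted p = 0.83 with an estimated correlation.

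Markers of other cell types were compared at day 1. Dendritic cell markers were at 4.47 ± 0.16 against 3.90 ± 0.23 (mean log2(FPKM + 1), SD, n = 6 each, two-sided exact permutation p = 0.0022, adjusted p = 0.031), and of 16 such genes 9 rose and 0 fell (11 and 0 adjusted over the list alone), with 1.61 for Fscn1 and 0.75 for Clec9a (medians 0.53 and 0.32 in the 2 sets). For the dendritic cell markers, camera gave adjusted p = 4.1e-07, and adjusted p = 0.13 with an estimated correlation. T and NK cell markers were at 4.71 ± 0.61 against 3.94 ± 0.54 (two-sided exact permutation p = 0.050, adjusted p = 0.10), and of 19 genes 5 rose and 0 fell (7 and 0 adjusted over the list alone). For the T and NK cell markers, camera gave adjusted p = 8.2e-07, and adjusted p = 0.41 with an estimated correlation. The granzyme genes Gzmb and Gzma rose by 2.28 and 2.06 (medians of the list 1.08 and -0.26). Of 12 macrophage markers, 1 rose and 4 fell (2 and 8 adjusted over the list alone), with -0.63 for Csf1r and -0.70 for Adgre1 (medians -0.62 and -0.11). For the macrophage markers, camera gave adjusted p = 0.0077, and adjusted p = 0.56 with an estimated correlation. Erythroid and platelet markers were at 0.83 ± 0.04 against 0.93 ± 0.08 (two-sided exact permutation p = 0.045, adjusted p = 0.10).

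In all, limma called 617 genes higher and 545 lower with lactate at day 1. The split was 561 higher and 672 lower after quantile normalization and 662 higher and 391 lower with the acinar markers removed. Fitted on the 12 libraries alone the count was 0 by limma, with 2282 genes at an unadjusted p under 0.05, so no gene named here as passing did so in that fit. Voom on the recovered fragments of all libraries called 1164. With the lymphocyte covariate, chosen after the data were seen, 815 were called (485 higher and 330 lower), 642 of them among the 1162. Single libraries moved the count of 1162 as well: 191 without D1 AP+PBS 1, 210 without D1 AP+PBS 4, 2380 without D1 AP+PBS 5, 643 without D1 AP+Lac 1, 646 without D1 AP+Lac 3, 696 without D1 AP+Lac 4 and 2217 without D1 AP+Lac 6. Of the 44 genes named here that passed, 36 still passed without D1 AP+Lac 1, 38 still passed without D1 AP+Lac 2, 36 still passed without D1 AP+Lac 3, 37 still passed without D1 AP+Lac 4, 43 still passed without D1 AP+Lac 5, 16 still passed without D1 AP+PBS 1, 41 still passed without D1 AP+PBS 2, 39 still passed without D1 AP+PBS 3, 18 still passed without D1 AP+PBS 4 and 38 still passed without D1 AP+PBS 6.

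**Figure D1:**
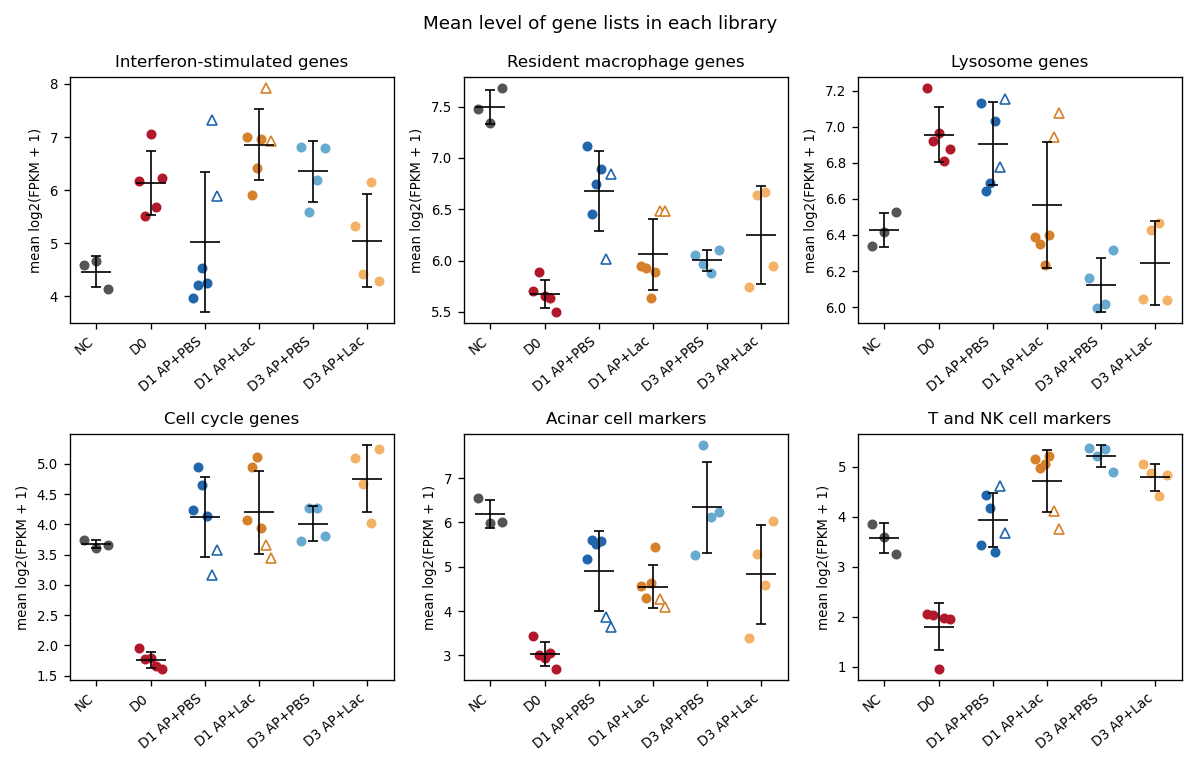
Mean log2(FPKM + 1) of 6 gene lists in each library (vertical axes) for the 6 groups (horizontal axes). Points are libraries, open triangles the day 1 libraries numbered 5 and 6, and black marks the group mean ± SD. The interferon-stimulated genes averaged 7.32 in D1 AP+PBS 5, 5.88 in D1 AP+PBS 6 and 3.97 to 4.53 in D1 AP+PBS 1 to 4.

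At day 3 few genes passed the test between lactate and PBS. Cpa3 (NCBI Gene ID 12873), a mast cell and basophil carboxypeptidase, was at 11.4 ± 10.6 (SD, n = 4) FPKM with lactate and 1.01 ± 0.849 (SD, n = 4) with PBS (log2 fold change 2.39, SE 0.42, adjusted p = 0.014). The lactate mean was 6.16 without D3 AP+Lac 4 (at 27.3) and the PBS mean 0.607 without D3 AP+PBS 4 (at 2.22). The log2 fold change was 1.89 (adjusted p = 0.044) without D3 AP+Lac 4, 2.26 (adjusted p = 0.068) without D3 AP+PBS 1 and 2.25 (adjusted p = 0.066) without D3 AP+PBS 2. Other genes that rose were the disulfide isomerase gene Pdia4, Txndc11, Ckap4, the unfolded-protein response regulator Xbp1 and the fucosyltransferase gene Fut8 (log2 fold changes 1.00, 1.11, 1.03, 0.84 and 0.82). The rest of the 10 highest were Pon3 (0.96), S1pr2 (0.91), C2cd2l (0.85) and Tmem214 (0.63). The 8 lowest that met the naming rule were Ifi27l2a (-1.41), Zfas1 (-1.24), Mir17hg (-1.15), Klrd1 (-0.91), Cirbp (-0.84), Poglut1 (-0.50), Tafazzin (-0.41) and Wdr53 (-0.41), Ifi27l2a being interferon-induced and Klrd1 a receptor of NK cells. The largest adjusted p among these 18 genes was 0.047 by limma. Arg1 averaged 73.7 ± 50.4 FPKM with lactate and 15.3 ± 12.3 with PBS (SD, n = 4 each), a difference that did not pass (log2 fold change 1.90, SE 0.75, adjusted p = 0.19).

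Of 22 endoplasmic reticulum stress genes, 3 rose and 0 fell (14 and 1 adjusted over the list alone), with 0.60 for Edem1 beside Xbp1 and Pdia4. For the endoplasmic reticulum stress genes, camera gave adjusted p = 8.8e-08, and adjusted p = 0.54 with an estimated correlation. Hsp90b1 had a value of 0.90 and did not pass over all genes (adjusted p = 0.062). Among 27 interferon-stimulated genes, 0 rose and 0 fell (0 and 16 adjusted over the list alone). For the interferon-stimulated genes, camera gave adjusted p = 1.1e-10, and adjusted p = 0.54 with an estimated correlation. Isg15 and Usp18 had values of -2.26 and -1.94 and the median was -1.28. Of 31 cell cycle genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.77 and a value of 1.21 for the proliferation marker Mki67. For the cell cycle genes, camera gave adjusted p = 1.3e-09, and adjusted p = 0.54 with an estimated correlation. Of 21 glycolysis genes, 0 rose and 0 fell (5 and 1 adjusted over the list alone), with 0.68 for Pgam1 and 0.52 for Pfkl. For the glycolysis genes, camera gave adjusted p = 4.4e-05, and adjusted p = 0.54 with an estimated correlation. Among 28 reparative macrophage genes, 0 rose and 0 fell (0 and 4 adjusted over the list alone), and among 27 proinflammatory genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone). For the reparative macrophage genes, camera gave adjusted p = 0.38, and adjusted p = 0.83 with an estimated correlation. For the proinflammatory macrophage genes, camera gave adjusted p = 0.46, and adjusted p = 0.88 with an estimated correlation. Of 15 genes of lactate transport, sensing and conversion, 0 rose and 0 fell (2 and 1 adjusted over the list alone), with -0.34 for Mpc1 and 0.34 for Slc16a6, and of 24 resident macrophage genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone). For the lactate transport, sensing and conversion genes, camera gave adjusted p = 0.89, and adjusted p = 0.92 with an estimated correlation. For the resident macrophage genes, camera gave adjusted p = 0.076, and adjusted p = 0.79 with an estimated correlation. Of 17 histone acyltransferase and deacylase genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone). For the histone acyltransferase and deacylase genes, camera gave adjusted p = 0.93, and adjusted p = 0.98 with an estimated correlation.

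Markers of other cell types were compared in the same libraries. Of 30 acinar markers, 0 rose and 0 fell (0 and 28 adjusted over the list alone), with -2.17 for Reg1. For the acinar cell markers, camera gave adjusted p = 7.1e-19, and adjusted p = 0.54 with an estimated correlation. Per library they were at 4.82 ± 1.12 against 6.34 ± 1.03 with PBS (mean log2(FPKM + 1), SD, n = 4 each, two-sided exact permutation p = 0.086, adjusted p = 0.15, with 0.029 the smallest p possible). Mast cell, basophil and eosinophil markers were at 1.75 ± 0.35 against 1.02 ± 0.13 (two-sided exact permutation p = 0.029, adjusted p = 0.066), and of 10 genes 2 rose and 0 fell (5 and 1 adjusted over the list alone), with Fcer1a at 1.58. For the mast cell, basophil and eosinophil markers, camera gave adjusted p = 7.5e-05, and adjusted p = 0.54 with an estimated correlation. T and NK cell markers were at 4.79 ± 0.27 against 5.21 ± 0.22 (two-sided exact permutation p = 0.057, adjusted p = 0.10). Dendritic cell markers, at 4.52 ± 0.17 against 4.89 ± 0.15, gave the same exact p and adjusted p, and of 16 genes 0 rose and 0 fell (0 and 4 adjusted over the list alone). For the dendritic cell markers, camera gave adjusted p = 0.0089, and adjusted p = 0.54 with an estimated correlation. B and plasma cell markers were at 6.05 ± 0.56 against 5.56 ± 0.35 (two-sided exact permutation p = 0.20, adjusted p = 0.29), and of 12 genes 0 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.13. For the B and plasma cell markers, camera gave adjusted p = 0.39, and adjusted p = 0.88 with an estimated correlation. Singled out after the values were seen, the plasma cell genes Jchain and Mzb1 had values of 3.14 and 2.24 that did not pass the test (adjusted p = 0.13 and 0.14).

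limma called 23 genes higher and 22 lower at day 3, and 2144 passed an unadjusted p of 0.05. A fit of the 8 libraries alone called 8 genes, of which 0 were among these 45, so no gene named here as passing did so in that fit. Of the 45, 24 were among the 24 called with voom, 41 among the 213 after quantile normalization and 40 among the 434 with the acinar covariate. The split was 50 higher and 26 lower after median-ratio scaling and 33 higher and 12 lower with the acinar markers removed. Left-out libraries gave 0 without D3 AP+PBS 1, 5 without D3 AP+PBS 2, 118 without D3 AP+PBS 3, 24 without D3 AP+PBS 4, 7 without D3 AP+Lac 1, 5 without D3 AP+Lac 2, 163 without D3 AP+Lac 3 and 19 without D3 AP+Lac 4, the 0 by limma standing beside 1692 genes at an unadjusted p under 0.05. Of the 20 genes named here that passed, 5 still passed without D3 AP+Lac 1, 4 still passed without D3 AP+Lac 2, 5 still passed without D3 AP+Lac 4, 0 still passed without D3 AP+PBS 1, 3 still passed without D3 AP+PBS 2 and 12 still passed without D3 AP+PBS 4.

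**Figure D2:**
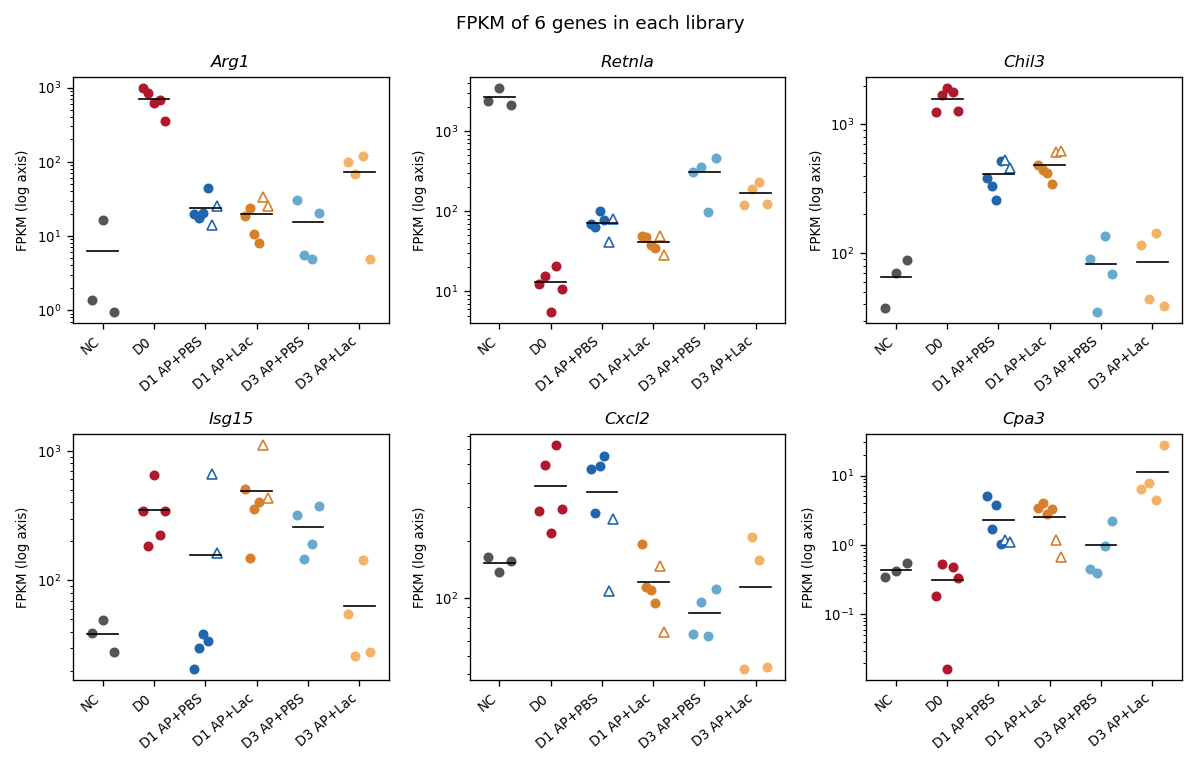
FPKM of 6 genes in each library (vertical axes, log scale) for the 6 groups (horizontal axes). Points are libraries, open triangles the day 1 libraries numbered 5 and 6, and black lines group means. Cpa3 averaged 11.4 FPKM in D3 AP+Lac (6.16 without D3 AP+Lac 4 (at 27.3)) and 1.01 in D3 AP+PBS.

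The lactate effect itself differed between the days. For interferon-stimulated genes the day 3 effect minus the day 1 effect was -4.87 for Isg15, -4.73 for Ifit3, -4.84 for Ifit3b and -4.54 for Rsad2 on the log2 scale, and it was -4.93 for Ly6i (largest adjusted p among these 5 = 0.011). In the other direction the differences were 2.25 for Cpa3, 2.06 for Tpsb2, 2.04 for Gdf15, 2.03 for Sdc1 and 1.98 for Stab1, where Tpsb2 is a mast cell tryptase gene and Sdc1 encodes syndecan 1 (largest adjusted p = 0.025). Of 27 interferon-stimulated genes 24 had a lower effect at day 3 and 0 a higher one (26 and 0 adjusted over the list alone, camera adjusted p = 3.5e-20, and adjusted p = 0.45 with an estimated correlation). For 22 monocyte genes, 7 were lower and 1 higher (8 and 2 adjusted over the list alone, camera adjusted p = 0.0060, and adjusted p = 0.56 with an estimated correlation), with -3.38 for Ly6c2 and -2.91 for Plac8. For 24 resident macrophage genes, 4 were higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 4.2e-06, and adjusted p = 0.51 with an estimated correlation), with 1.59 for F13a1 and 1.38 for Gas6. The macrophage genes Csf1r, Adgre1 and Mrc1 had differences of 1.09, 1.22 and 1.37. Arg1, at 2.17, did not pass (adjusted p = 0.15).

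The interaction passed for 1280 genes, 569 with a higher and 711 with a lower effect at day 3. The split was 798 higher and 746 lower after quantile normalization and 994 higher and 780 lower with the lymphocyte covariate. The count was 3408 without the day 1 libraries numbered 5 and 6 and 546 in a fit of the 4 groups concerned (545 of them among the 1280), and single libraries gave 746 without D1 AP+PBS 1, 766 without D1 AP+PBS 4, 2262 without D1 AP+PBS 5, 2154 without D1 AP+Lac 6, 799 without D3 AP+PBS 1 and 622 without D3 AP+Lac 2. Of the genes called at both days, 5 in all, 1 had the same direction, and across 11960 genes the 2 lactate effects, which share no libraries, had a correlation of -0.367; genes are not independent replicates.

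The last comparison asked whether the day 1 lactate effect had the direction of the later recovery step, from day 1 to day 3 with PBS. Interferon-stimulated, antigen presentation and dendritic cell genes had positive medians in both (1.88 and 1.34, 0.28 and 0.66, 0.43 and 1.00), and resident macrophage and lysosome genes negative ones (-0.61 and -0.66, -0.33 and -0.76). The acinar markers (-0.41 and 1.51), the islet markers (-0.06 and 1.51, from the 1 islet gene tested) and the cell cycle genes (0.11 and -0.13) had medians of opposite sign, as had Retnla (-0.77 and 1.92) and Chil3 (0.25 and -2.42), which did not pass at day 1. The islet marker level at day 3 with PBS was high in D3 AP+PBS 2 alone (1.09 against 0.076 to 0.18 in the others). Of the 34 list medians, of which that of the islet markers rests on 1 gene and that of the erythroid and platelet markers on 3, 31 had the same sign, where simulated unchanged groups sharing controls, with genes drawn independently, gave 19.9 on average. With the controls split as described next the mean was 26.9 (range 22 to 30). Across 11960 genes the 2 sets of log2 fold changes had a correlation of 0.736 and a covariance of 0.111. Both comparisons use the same 6 day 1 PBS libraries, and 100 simulations of unchanged groups against such controls gave a mean correlation of 0.446 and a mean covariance of 0.0133. With the controls split 3 and 3 over 20 ordered splits, the correlation averaged 0.592 (range 0.274 to 0.737) and the covariance 0.0931. Genes are not independent replicates, so these values are descriptive. Per library, marker means of T and NK cells (0.77 and 1.27), dendritic cells (0.57 and 0.98) and macrophages (-0.29 and -0.80) also moved alike in both. Acinar (-0.34 and 1.44) and islet means (-0.0085 and 0.26) moved in opposite directions. Among these only the dendritic cell means passed in both. The correlation was not adjusted for cell content, so a shared shift in it was not separated from a change within macrophages.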

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

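Of the tests here, those within the day 1 libraries 1 to 4 and 5 and 6, of acinar RNA and of other splits of the libraries were chosen after the results were seen, and the plasma cell markers were chosen after the day 3 values of some of them had been seen. The margins used for the exchanged labels and for plasma cell RNA, 1 SD and 1 standard error, were set after the values were seen.

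In 9 of 145 groups of 4 to 6 libraries, 1 library lay far from the others on the log2(FPKM + 1) scale by Dixon's gap ratio, and chance sets off this test in about 1 in 20 groups. These were islet cell markers in D0 4 (0.085, others 0.02 to 0.038), islet cell markers in D3 AP+PBS 2 (1.09, others 0.076 to 0.18), endothelial cell markers in D0 1 (0.86, others 0.60 to 0.67), T and NK cell markers in D0 3 (0.97, others 1.96 to 2.06), erythroid and platelet markers in D1 AP+PBS 5 (0.76, others 0.94 to 0.98), Csf1r in D3 AP+PBS 2 (7.80, others 8.16 to 8.23), Ly6c2 in D0 2 (9.90, others 10.30 to 10.46), Nos2 in D1 AP+PBS 5 (1.83, others 0.0089 to 0.11) and Xbp1 in D0 1 (7.14, others 7.46 to 7.57).

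The lactate effect differed between the days in 1280 genes by the interaction test. Of 82 genes named in the 2 lactate comparisons, those that passed it are given here. Many were named for a large lactate effect at 1 of the days, which is a term of this difference. Their signs are therefore no separate evidence of a reversal. Among the named genes, the day 3 effect minus the day 1 effect was negative on the log2 scale for Clec9a -0.99, Cxcl10 -4.17, Fscn1 -3.08, Gzma -3.39, Gzmb -2.30, Ifi205 -3.12, Ifit2 -4.48, Ifit3 -4.73, Isg15 -4.87, Ly6c2 -3.38, Ly6i -4.93, Pdcd1lg2 -1.21, Plac8 -2.91, Slfn4 -4.45, Socs2 -1.54, Tap1 -1.07, Tap2 -0.76, Tgtp1 -3.99, Zbp1 -3.09, Ifi27l2a -2.23, Klrd1 -1.37, Mir17hg -1.62, Poglut1 -0.74, Tafazzin -0.45, Usp18 -3.82, Wdr53 -0.45 and Zfas1 -1.56. It was positive for Adgre1 1.22, Csf1r 1.09, F13a1 1.59, Gas6 1.38, Gdf15 2.04, Gdpd1 1.30, Jdp2 1.14, Jun 0.87, Mrc1 1.37, Npc1 0.93, Sirt2 0.51, Stab1 1.98, C2cd2l 1.06, Ckap4 1.26, Cpa3 2.25, Edem1 0.52, Fcer1a 1.43, Fut8 0.96, Pdia4 0.87, Pon3 1.47, S1pr2 0.94, Slc16a6 0.53, Tmem214 0.82, Txndc11 1.21 and Xbp1 0.83.

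Interferon-stimulated genes were higher with lactate at day 1, with a difference in list mean of 1.83 over 6 against 6 libraries (two-sided exact permutation p = 0.022). Each treatment held 2 libraries numbered 5 and 6, so a division that shifts both treatments alike is balanced by the design. The median log2 fold change was 2.42 within numbers 1 to 4 (list mean difference 2.33, SE 0.28, exact permutation p = 0.029, the smallest that 70 arrangements can give) and 0.91 within numbers 5 and 6. RNA of T, NK and dendritic cells cannot be told apart from a change within macrophages: the interferon list rose by 1.05 more than the larger of those marker lists, but with an exact permutation p of 0.13 (1.07 and 0.057 within numbers 1 to 4). Marker means rose by 0.77 for T and NK cells and 0.55 for the 15 dendritic cell genes outside the interferon list. RNA of such markers was present in spite of the macrophage sort, with T and NK cell markers at a mean log2(FPKM + 1) of 4.71 with lactate and 3.94 with PBS. An effect of lactate itself remains open as a hypothesis, and at day 3 the list differed by -1.30 (exact permutation p = 0.057).

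The library D1 AP+PBS 5 lay with the lactate libraries, with an interferon list mean of 7.32. It was not the only raised PBS library, as D1 AP+PBS 6 was at 5.88 against 3.97 to 4.53 in D1 AP+PBS 1 to 4. On an axis from PBS (0) to lactate (1) made from numbers 1 to 4 D1 AP+PBS 5 scored 0.95, above the lowest left-out lactate score of 0.81, and D1 AP+PBS 6 scored 0.23. A single wrong label of D1 AP+PBS 5 would give such a score. The score largely restates that this library lay with the lactate ones, so it lends a wrong label no separate support. An exchange with a lactate library would need a partner: D1 AP+Lac 6 scored 0.52 and the highest left-out PBS library 0.33, a gap within the SD of 0.30, so an exchange stays open. The interferon list mean of D1 AP+Lac 6 points the other way. At 6.93 it was above D1 AP+PBS 6 (5.88) and the lowest lactate library, D1 AP+Lac 2 (5.91). By the bound as first written, without that SD, the exchange would have counted as excluded. The labels were kept as given (without this library 2380 genes were called against 1162), and variation between animals, a biological explanation, was not tested.

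At day 3, the endoplasmic reticulum stress genes had a median log2 fold change of 0.48 with lactate and the acinar markers one of -1.74, although 3 of 22 and 0 of 30 genes passed over all genes by limma. Adjusted over the list alone, 14 of the former rose and 28 of the latter fell. With the acinar covariate the median did not fall, being 0.60 (SE 0.13 over the genes of the list), and 9 of 22 genes passed against 3. That covariate raised the calls over all genes from 45 to 434, so the rise to 9 is not particular to this list. The median goes against lower acinar RNA as the cause of the first part, without a measure of the spread between libraries. Plasma cell RNA may contribute, and RNA of such markers was present in spite of the macrophage sort. The mean of 4 plasma cell markers was 5.63 ± 0.70 with lactate and 3.65 ± 0.72 with PBS (SD, n = 4 each, exact permutation p = 0.029). With that mean as a covariate the median was 0.235 (SE 0.10 over the genes of the list). In that fit 2 of 22 genes passed, while 565 were called over all genes. By the bound as first written, 0.239, this would have counted for plasma cell RNA, but the gap is within the standard error. Both standard errors treat genes as independent replicates and leave out the spread between libraries. Plasma cell RNA and a change within macrophages therefore cannot be told apart.

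Whether chance could give the counts was tested by other splits of the libraries. For lactate at day 1 4 of 100 splits gave as many genes (1162 for the real split, at most 3064 for another); the highest exchanged D1 AP+PBS 3 and 5 with D1 AP+Lac 5 and 6. At day 3 2 of 35 splits gave as many genes (45 for the real split, at most 754 for another), so chance cannot be excluded there, and the highest exchanged D3 AP+PBS 3 with D3 AP+Lac 3. For the interaction 2 of 100 splits gave as many genes (1280 for the real split, at most 3307 for another), the highest making this exchange and that of D1 AP+PBS 5 with D1 AP+Lac 6, the exchange left open above, with all other labels as given. In all of these the highest count exceeded the real one, at day 3 by several times, and the cause was not tested. For day 0 against NC the real split, 1 of 56, gave more genes than any other (7309 against at most 2023). The same held for day 1 PBS against day 0 (1 of 100 splits, 7521 against at most 6659). It also held for day 3 PBS against day 1 PBS (1 of 100 splits, 4103 against at most 3386). For day 3 PBS against NC the real split was again the highest (1 of 35 splits, 2535 against at most 1026). Chance is thus an unlikely source of these counts. The shares of 0.04 for lactate at day 1 and 0.02 for the interaction come from drawn splits that did not keep the day 1 libraries 1 to 4 and 5 and 6 apart. Of 100 splits drawn within that division, the real one included, 3 gave as many genes for lactate at day 1 (at most 1914 for another). For the interaction 2 did (at most 1524). These shares lie under 0.05, but narrowly and without adjustment over the comparisons. Other splits gave more genes than the real one in both, so chance is made less likely and is not excluded.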

How the results depend on the processing

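The tests with voom, the lymphocyte covariate, the day 1 libraries numbered 5 and 6, and the scaling of cell type content were chosen after the data were seen. The 199 named gene results gave 4993 values over all settings, of which 4496 kept their direction and side of the threshold, 455 no longer passed, 36 newly passed and 6 changed sign. The sign changes were Pou2af1 in D1 PBS against D0 with the lymphocyte covariate (-0.057) and, with the day 1 libraries numbered 5 and 6 alone, Cxcl9 -0.0040, Ly6i -0.25, Pdcd1lg2 -0.023, Pltp 0.041 and Stab1 0.12. Counts of genes that moved by over 1.5 times were, for lactate at day 1 (1162), 616 with no filter, 4591 with quality weights, 0 in the 2 groups alone (limma, 2282 at an unadjusted p under 0.05), 3426 without numbers 5 and 6 and 0 with these alone (394 of 11960 unadjusted, a share under 0.05, where fewer libraries enter). For day 3 (45) they were 11 with a pseudocount of 0.1, 104 with no filter, 21 with the stricter one, 213 and 76 with quantile and median-ratio scaling, 434 and 381 with the acinar and lymphocyte covariates, 470 with quality weights, 8 in the 2 groups alone (0 among the 45) and 24 with voom. For the interaction (1280) they were 3684 with quality weights, 546 in its own groups and 3408 without numbers 5 and 6. For day 0 against NC the acinar covariate gave 3474 (7309), and for day 1 PBS against day 0 the acinar and lymphocyte covariates gave 4992 and 4659 (7521). The lymphocyte covariate gave 1689 for day 3 against day 1 PBS (4103), and quality weights 4489 for day 3 PBS against NC (2535). List calls went from 104 to 0 with an estimated correlation, the trajectory correlation from 0.736 to 0.592 with split controls, and cell type content calls from 11 to 26 with median-ratio scaling. Leaving out 1 library at a time gave 191 to 2380 genes for lactate at day 1, 0 to 163 genes for lactate at day 3, 622 to 2262 genes for the interaction, 6181 to 7079 genes for day 0 against NC, 7027 to 7543 genes for day 1 PBS against day 0, 2996 to 4660 genes for day 3 against day 1 PBS and 1188 to 2335 genes for day 3 PBS against NC. Whether equal replicate numbers pair the libraries is not known, and the values did not settle it. At day 1, 4 of 6 same-numbered pairs had deviations correlated above 0.1 (-0.340 to 0.610), and at day 3 1 of 4 had (-0.534 to 0.276). Only 2 and 0 correlated best with their own number. In fits of the compared groups alone, the number as a block gave 154 genes against 0 for lactate at day 1 (135 higher and 19 lower, 132 of them among the 1162), 4 against 8 at day 3 (0 among the 45) and 463 against 546 for the interaction (115 higher and 348 lower). The blocked counts of the other comparisons were within 1.5 times of the original. With the lymphocyte covariate the more frequent direction turned for day 0 against NC (2759 higher and 2372 lower), day 1 PBS against day 0 (1885 higher and 2774 lower), day 3 against day 1 PBS (797 higher and 892 lower) and the interaction. For lactate at day 1 that covariate gave 815 genes, within 1.5 times of the original, but only 642 of them were among the 1162. Apart from the settings with fewer libraries or genes, the cause was not tested.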

Other observations

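All the tests in this part were chosen after the data were seen. Over 315 KEGG pathways of 10 to 300 genes, tested with camera as for the lists, the proteasome pathway (45 genes, 9 rose and 0 fell) ranked higher with lactate at day 1 (median log2 fold change 0.16, adjusted p = 1.3e-06, and adjusted p = 0.84 with an estimated correlation). The peroxisome pathway (68 genes, 1 rose and 9 fell) ranked lower (median log2 fold change -0.12, adjusted p = 1.8e-04, and adjusted p = 0.64 with an estimated correlation). At day 3 the ribosome pathway (132 genes, of which 0 fell by limma) ranked lower (median log2 fold change -0.33, adjusted p = 6.3e-17, and adjusted p = 0.82 with an estimated correlation). Ribosomal protein genes held 10.7 to 13.7% of the summed FPKM in the 4 day 3 libraries with lactate and 13.5 to 17.0% in the 4 with PBS. The proteasome pathway also ranked higher at day 0 than in NC, where 37 of 45 genes rose and 1 fell (median log2 fold change 0.69, adjusted p = 2.8e-14, and adjusted p = 0.98 with an estimated correlation).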
